A study of Mus musculus with 11 samples.

How the data were processed

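Polyadenylated RNA of injured mouse arteries was sequenced on an Illumina instrument as paired reads, per the labels' protocols, with tissue taken on day 7 after injury. The 11 libraries form 4 groups: femoral control (3), femoral knockout (3), carotid control (3) and carotid knockout (2). The deposited table holds raw gene counts, whole numbers for 48897 genes in 11 libraries, with no other value columns. HISAT2, HTSeq, DESeq, DESeq2 and edgeR are listed, without version or role, per the submitters' processing notes, and no record states a strand setting for the counting. These notes name the mouse assembly mm9, while the positions in the table match GRCm38: of 39064 genes joined by NCBI gene ID to the GRCm38 RefSeq annotation, 99.8% overlap the annotated position and 72.1% share its start. Positions are therefore given as GRCm38. A spreadsheet had turned 27 symbols into dates, and all 27 were restored from the NCBI gene ID. Trim22, Plin2, Hbb-b1 and Hbb-b2 were list genes not in the table and were not analysed here.

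Library totals lay between 43698644 and 55998563 counts. Col3a1 was the gene with most counts in each library, at 1.07 to 2.85%, mitochondrial genes took 1.83 to 3.32% and ribosomal RNA 0.107 to 0.297%. Protein-coding genes took 97.5 to 98.0%. A count of 0 was read as allowing up to 3 counts, and such floors cover counting error only, since reads from amplified libraries are not independent molecules. Levels are counts scaled to library size (CPM), computed here with the trimmed mean of M-values, whose factors ran from 0.963 to 1.03.

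Gene tests used edgeR 4.0.16 under R 4.3.3, with limma 3.58.1 and DESeq2 1.42.0 for list tests and alternatives and Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 for tables and figures. All 11 libraries entered 1 quasi-likelihood fit with a mean for each of the 4 groups and 7 residual degrees of freedom. Expression filtering by edgeR's filterByExpr kept 21343 genes (43.6%), and the common biological coefficient of variation was 25.6%. Contrasts were femoral knockout against control, carotid knockout against control, the carotid minus the femoral effect, and carotid control against femoral control. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. Genes called in both knockout comparisons were set against the number expected from the 2 counts with Fisher's exact test, which takes the vessels as independent, as does the fit. Errors are SD for group means and SE for fitted log2 changes. The SE was derived from the test, as the absolute log2 change divided by the square root of its F statistic.

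There were 40 gene lists, 20 of processes and 20 of cell types and surrounding tissues. Process lists cover contractile and modulated smooth muscle, cell cycle, collagen and elastic matrix, matrix proteases, growth factors, cytokines, interferon, the TRIM family, CNC factors, antioxidant response, NADPH oxidase, proteasome, autophagy, oxidative phosphorylation, glycolysis, cholesterol synthesis, lipid handling, unfolded protein response and immediate early genes. Lists were tested with camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2, for lists of at least 5 tested members, which left out thyroid and parathyroid. Adjustment was over the lists of a comparison, and camera with an estimated correlation and fry were alternatives. Counts of members are given over all genes tested and adjusted over the list alone.

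Genes named in the text were chosen by a rule. Nfe2l3 and Trim5 were always named. Each knockout comparison adds the 8 largest rises and 8 largest falls among genes with adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the libraries of the 2 groups. Names of predicted genes (Gm with a digit, Rik), pseudogenes and immunoglobulin or T cell receptor segments were left out there. A list that passed camera, or with at least 3 called members, adds its 4 members of smallest p, and any other list up to 2. The difference between vessels adds up to 5 genes per direction, the shared response up to 10, and the controls 3 per passing list. Lists, contrasts and the rule were fixed before the data were examined, as were the tests of genes and lists. Of the alternatives, 3 were chosen after the data were seen: a covariate for the level of skeletal muscle genes, a fit of protein-coding genes only, and limma-voom with same-numbered libraries of the 2 vessels allowed to correlate. Tests of explanations chosen after the result was seen are named where they are reported. Named outside the rule, after their values were seen, were Lif, Cd8a, Cd8b1, Trim30a, Trim30b, Trim30c, Trim30d and the clock genes other than Npas2 and Arntl.

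Replicate numbers were checked for pairing by correlating deviations from the group mean between control and knockout libraries of the same number. In the femoral artery r was 0.17, 0.18 and 0.12, against −0.18 to 0.01 for libraries of differing number. Deviations from a group mean depend on each other, so these few values cannot establish pairing. Fits with the number as a block are therefore given as alternatives only. In the carotid artery r was −0.12 and −0.15 with the numbers of the titles, and −0.12 and 0.02 with those of the descriptions, where the carotid knockouts are numbered differently. Both blocks number the femoral libraries alike and also block the carotid libraries, in a fit that estimates the spread over both vessels. With the numbers of the titles 1224 femoral and 61 shared genes passed, and with those of the descriptions 1261 and 113. Femoral Nfe2l3 had an adjusted p of 0.0501 and 0.0492, and Trim12c passed at 0.0115 and 0.00814. The femoral call of Gbp2b ended with both (0.055 and 0.0589), while those of Cd34 (0.0676 and 0.0426), Cd5 (0.0573 and 0.0203) and Hk2 (0.0507 and 0.0459) ended with the titles only.

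The gene test was tested on simulated counts with 200 changed genes drawn from the means and totals of these libraries. For the femoral comparison, run on 20704 genes, 64% of 2-fold and 92% of 4-fold changes were recovered and 8 of 164 calls were false. For the carotid comparison, run on 20714 genes, these were 59% and 93%, with 5 of 157 calls false. The changed genes had a mean of at least 1 CPM, and each gene was drawn independently of the others. Variation shared by many genes of a library was not simulated, so these rates need not hold for the real libraries or for lower genes. Alternatives were size factors by relative log expression, library totals alone, no filter beyond 1 read, a mean of at least 5 CPM, DESeq2, limma-voom, robust estimation of the spread, replicate blocks by title and by description number, only the libraries of a comparison, a fold threshold, and each library left out in turn. Where leaving out a carotid knockout library leaves 1, that sample was assumed to vary like the other groups.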

Results

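Messenger RNA was sequenced from injured mouse arteries collected on day 7 after the injury, in mice lacking Nrf3 and in control mice carrying floxed alleles. Nrf3 is a transcription factor of the CNC family, encoded by Nfe2l3. Femoral arteries had been injured with a wire (3 control and 3 knockout samples), and carotid arteries had been ligated (3 control and 2 knockout samples). The design asks which genes respond to Nrf3 loss while the injured wall remodels, with the series title placing Trim5 beside Nrf3 in smooth muscle dysfunction and neointimal thickening. Library totals ran from 43698644 counts in femoral knockout replicate 2 to 55998563 in femoral control replicate 3, and carotid totals from 47986275 to 54818855. Each knockout library, at 49671909 counts or fewer, lay below each control library, at 51067573 or more. Of the variance between libraries, 32.5% lay on a component that separated the vessels, and 21.3% on a component where the 6 controls sat at 12.8 to 57.7 and the 5 knockouts at −63.3 to −15.3. The labels do not say whether replicates are separate animals, so the p-values measure spread between these samples.

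The targeted gene was read in every library. Nfe2l3 (NCBI gene 18025; chromosome 6, 51432670 to 51458768, plus strand, GRCm38) had 48, 81 and 37 counts in the femoral controls and 11, 2 and 0 in the femoral knockouts. In the carotid artery it had 57, 75 and 85 counts in the controls and 9 and 8 in the knockouts. Mean level went from 1.08 ± 0.505 CPM (SD, n = 3) to 0.0926 ± 0.123 CPM (n = 3) in the femoral artery, and from 1.36 ± 0.227 (n = 3) to 0.171 ± 0.0204 CPM (n = 2) in the carotid artery. The count of 0 in femoral knockout replicate 3 allows up to 0.0622 CPM, from counting error only. Every knockout library lay below every control library of its vessel. The femoral fall of −3.50 ± 0.78 on the log2 scale (SE) passed in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.0472. It missed the threshold without femoral control replicate 1 (adjusted p 0.0755), 2 (0.160) or 3 (0.112), without femoral knockout replicate 2 (0.162), and without any 1 of the 5 carotid libraries (0.0510 to 0.0626). Without femoral knockout replicate 1 the femoral change of Nfe2l3 was −5.48 (adjusted p 0.0265), and without replicate 3 it was −2.90 (adjusted p 0.0308). The carotid value, −2.97 ± 0.86, did not pass in edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p 0.142) and was −3.00 with adjusted p 0.00312 in DESeq2. The labels do not say which part of the gene was removed.

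Trim5, which encodes a factor that restricts retroviruses, fell in both vessels (NCBI gene 667823; chromosome 7, 104263386 to 104288415, minus strand, GRCm38). Its level went from 7.55 ± 1.46 to 0.415 ± 0.0262 CPM in the femoral artery and from 7.90 ± 0.31 to 0.85 ± 0.736 CPM in the carotid artery. These are log2 changes of −4.18 ± 0.42 and −3.21 ± 0.46, with adjusted p of 0.00123 and 0.0119 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The neighbouring paralog Trim12a went from 18.0 ± 1.93 to 0.159 ± 0.24 CPM in the femoral artery (−6.76 ± 1.08, adjusted p 0.0173) and from 16.9 ± 2.66 to 1.31 ± 1.80 CPM in the carotid artery (−3.68 ± 1.02, adjusted p 0.125). Carotid knockout replicate 2 held 132 Trim12a counts and replicate 1 held 2; without replicate 2 the carotid change was −8.60 with adjusted p 0.0200. The femoral Trim12a call was lost without femoral control replicate 2 (adjusted p 0.0533) or 3 (0.0532) and without femoral knockout replicate 1 (0.0803) or 2 (0.0776). Another paralog, Trim12c, went the other way, from 43.5 ± 6.29 to 68.2 ± 6.11 CPM (0.65, adjusted p 0.0512) and from 37.0 ± 5.55 to 69.4 ± 13.6 CPM (0.91, adjusted p 0.0329). That carotid Trim12c rise was lost without carotid control replicate 2 (adjusted p 0.0579) or 3 (0.0999), without carotid knockout replicate 1 (0.239), and without femoral control replicate 2 (0.0568), femoral knockout replicate 1 (0.0529) or 2 (0.0571). Next to them Trim34a fell by 2.21 and 1.77 on the log2 scale, while Trim34b rose by 4.62 and 4.81 from 0.122 and 0.143 CPM. Summed over Trim5, Trim12a and Trim12c, the femoral level was 69.0 ± 9.29 CPM in the controls and 68.8 ± 5.89 CPM in the knockouts, and the carotid level 61.8 ± 8.05 and 71.6 ± 11 CPM. These genes are near-identical in places, so the split of reads between them is uncertain.

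**Figure D1:**
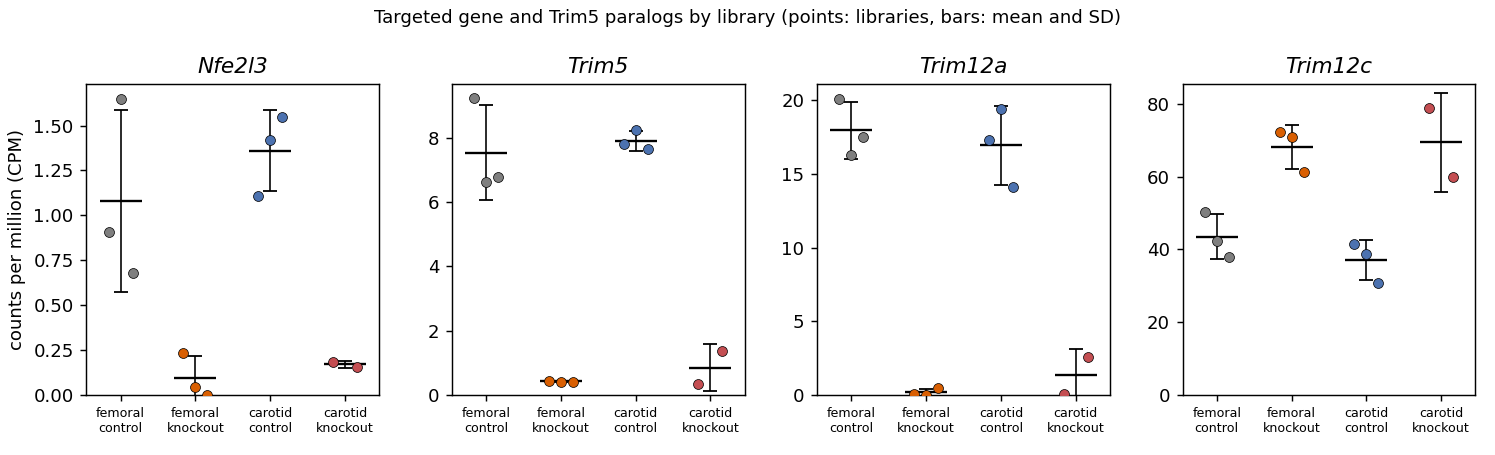
Level of Nfe2l3, Trim5 and the Trim5 paralogs Trim12a and Trim12c in each library, in CPM, with the mean and SD of each group. Nfe2l3 and Trim5 were lower in every knockout library than in any control library of the same vessel.

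In the wire-injured femoral artery, the lists of cytokine and of T and NK cell genes stood higher in the knockout and the list of collagen and elastic matrix genes lower, by camera at its preset correlation. With the correlation estimated from the data these lists did not pass (Benjamini-Hochberg adjusted p 0.734, 0.658 and 0.734, in that order). In fry, the other alternative, T and NK cell genes passed (adjusted p 0.0448). Cytokine genes (fry adjusted p 0.0853) and collagen and elastic matrix genes (0.25) did not. All 37 inflammatory cytokine genes tested had positive changes, with a median of 1.13 on the log2 scale, and all 18 T and NK cell genes did, with a median of 1.37. Collagen and elastic matrix genes had a median of −0.33, with 29 of 33 negative: Postn, a matrix protein of the remodelling wall, fell from 796 ± 181 to 359 ± 102 CPM, and the collagen chaperone Serpinh1 from 1990 ± 71.3 to 1400 ± 184 CPM. Arginase, encoded by Arg1 and typical of wound macrophages, rose from 6.63 ± 0.523 to 89.3 ± 42.0 CPM (n = 3 and 3). Of 21343 genes tested, 393 rose and 142 fell at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test, 269 and 76 of them by at least 2-fold.

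The largest femoral rises among genes of at least 5 CPM included those of Hal (6.96 ± 0.66, histidine ammonia-lyase), Mup9 (6.90 ± 0.67), Gbp2b (4.68 ± 1.05), Gdpd3 (3.84 ± 0.44), Arg1 (3.75 ± 0.50), the immunoglobulin joining chain Jchain (3.58 ± 0.49) and Ubd (3.00 ± 0.57). Besides Trim5, Trim12a and Trim34a, the largest falls within the naming rule were Mup11 (−3.77 ± 0.64), the clock factor Npas2 (−2.48 ± 0.50) and Spon2 (−2.31 ± 0.32). The imprinted RNA H19 (−2.11 ± 0.42) and Angptl1 (−2.06 ± 0.36) followed, and some called predicted genes left out by the rule fell further. Mup9, Mup11 and Gbp2b have close relatives in the genome, and their counts are uncertain for that reason. Hal went from 0.108 ± 0.153 to 13.8 ± 2.59 CPM and Mup9 from 0.296 ± 0.192 to 35.4 ± 12.9 CPM. The count of 535 calls was 182, 78 and 85 without femoral control replicate 1, 2 or 3, and 99, 82 and 1317 without femoral knockout replicate 1, 2 or 3. Among 58 named genes these omissions ended 27, 36, 39, 35, 38 and 6 femoral calls, in the same order, and reversed none. A covariate for the level of skeletal muscle genes, chosen after the data were seen, left 143 femoral calls and ended 33 of the 57 calls among these genes.

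Cytokine genes rose as a set in the femoral knockout (camera, Benjamini-Hochberg adjusted p 7.96e-15; p 0.734 with the correlation between genes estimated from the data). Among them Ccl5 went from 7.51 ± 2.24 to 27.1 ± 1.37 CPM and Cxcl12 from 608 ± 99.9 to 1150 ± 147 CPM, with Ccl6, Csf1 and Lif also called. Of the 37, 5 rose over all genes tested and 28 adjusted over the list alone. Interferon response genes had a median of 0.68 (camera adjusted p 4.05e-08; p 0.734 with the estimated correlation), with 2 rises over all genes and 14 adjusted over the list alone. Those 2 were the guanylate-binding genes Gbp4 (1.88 ± 0.35) and Gbp5 (1.68 ± 0.33), while Irf1 went from 65.0 ± 13.6 to 136 ± 41.7 CPM without passing. T and NK cell genes were also higher (camera adjusted p 8.89e-13; p 0.658 with the estimated correlation), with 7 of 18 called and 16 adjusted over the list alone. They include Cd3e of the T cell receptor complex (1.82 ± 0.27), Cd5 (1.56 ± 0.34), Themis (1.82 ± 0.32) and granzyme Gzmb (2.61 ± 0.46). B and plasma cell genes had a median of 0.55 (camera adjusted p 0.0110; p 0.734 with the estimated correlation), and Igkc, Jchain and Mzb1 rose, both over all genes and adjusted over the list alone. That list call was lost without femoral control replicate 3 (adjusted p 0.0640) or femoral knockout replicate 1 (0.0754).

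Macrophage genes (median 0.24, camera adjusted p 0.0180) and neutrophil genes (1.44, 0.00461) were also higher in the femoral knockout, each with p 0.734 under the estimated correlation. Csf1r, the receptor that maintains macrophages, went from 273 ± 10.8 to 487 ± 105 CPM and Itgam from 98.8 ± 20.4 to 197 ± 48.8 CPM; they were the 2 macrophage members called, with 6 adjusted over the list alone. No neutrophil member passed in edgeR's quasi-likelihood test over all genes, and 6 of 14 did adjusted over the list alone; Lcn2 went from 48.3 ± 25.7 to 203 ± 88.3 CPM (adjusted p 0.0585), and Csf3r from 35.5 ± 15.8 to 114 ± 50.9 CPM. Subunits of the phagocyte NADPH oxidase rose, namely Ncf1 (1.32 ± 0.25), Ncf4 (1.27 ± 0.25) and Rac2 (1.02 ± 0.21), as did their list (median 0.40, camera adjusted p 0.0180; p 0.734 with the estimated correlation; 6 of 12 adjusted over the list alone). Glycolysis genes had a median of 0.18 (camera adjusted p 0.0180; p 0.734 with the estimated correlation), with rises of Hk2 (0.70 ± 0.14), Pfkfb3 (0.65 ± 0.13) and the glucose carrier Slc2a1 (0.70 ± 0.15), and 4 rises and 1 fall adjusted over the list alone. The glycolysis call was lost without femoral control replicate 1 (adjusted p 0.230) or femoral knockout replicate 3 (0.104), and the macrophage call without femoral knockout replicate 2 (0.0768). Scavenger receptors of lipid-laden macrophages, Msr1 (1.49 ± 0.30) and Olr1 (1.24 ± 0.28), rose, though the lipid handling list did not pass (median 0.18, adjusted p 0.141). Mitochondrial superoxide dismutase, Sod2, rose from 93.6 ± 16.8 to 175 ± 30.8 CPM, and Bach1, a CNC relative that represses antioxidant genes, from 60.3 ± 7.70 to 98.7 ± 14.5 CPM.

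Collagen and elastic matrix genes fell as a set in the femoral knockout (camera adjusted p 0.000108; p 0.734 with the estimated correlation), with 2 of 33 called and 3 adjusted over the list alone. Elastin, Eln, went from 9120 ± 1970 to 5350 ± 312 CPM without passing (adjusted p 0.0758), and Sparc from 8490 ± 1000 to 6390 ± 494 CPM. Contractile smooth muscle genes had a median of −0.26, with 23 of 25 negative (camera adjusted p 0.0131; p 0.771 with the estimated correlation). No contractile member passed, over all genes or adjusted over the list alone; Tpm1 went from 1300 ± 136 to 931 ± 222 CPM, and Pln, Hspb6 and Myl6 changed by −0.68, −0.51 and −0.30. Contractile genes averaged 8.30, 8.22 and 8.21 log2 CPM in the femoral controls and 7.58, 7.92 and 8.34 in the knockouts, and the list was not called without femoral knockout replicate 1 (adjusted p 0.356) or femoral control replicate 1 (0.0514). Skeletal muscle genes fell in the same comparison, with a median of −1.98. With the covariate for their level, chosen after the data were seen, the contractile list was not called. Matrix proteases went both ways: Mmp3 (1.80 ± 0.37), Timp1 (1.22 ± 0.19) and Adamts1 (0.49 ± 0.10) rose and the plasminogen activator Plat fell (−0.90 ± 0.18), with 7 rises and 2 falls adjusted over the list alone. Tnfrsf11b, which encodes osteoprotegerin, fell by 1.19 ± 0.23, the Notch ligand Jag1 fell by 0.70 ± 0.14 and the growth factor Hgf rose by 0.66 ± 0.13. Adventitial fibroblast markers Cd34 (−0.57 ± 0.12) and Mfap5 (−0.71 ± 0.15) fell, with a list median of −0.43 (camera adjusted p 0.0507) and 1 rise and 6 falls adjusted over the list alone.

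Endothelial genes had a femoral median of −0.32 with 16 of 17 negative (camera adjusted p 0.00320; p 0.734 with the estimated correlation), and Sox18 went from 102 ± 11.8 to 67.5 ± 4.26 CPM (adjusted p 0.0610), the 1 member past the threshold adjusted over the list alone; Nos3, Kdr and Tek changed by −0.57, −0.44 and −0.42. Erythrocyte genes had a median of −1.31 (camera adjusted p 0.00320; p 0.734 with the estimated correlation) and Hbb-bt went from 546 ± 266 to 183 ± 54.1 CPM; 5 of 7 passed adjusted over the list alone. Skeletal muscle genes had a median of −1.98 (camera adjusted p 0.00461; p 0.751 with the estimated correlation), and their mean log2 level was 4.59, 7.60 and 6.26 in the femoral controls and 3.14, 6.06 and 3.96 in the knockouts. Muscle Eno3 went from 152 ± 116 to 29.8 ± 18.5 CPM, and the list was not called without femoral control replicate 2 (adjusted p 0.0715) or femoral knockout replicate 1 (0.0704). Cartilage genes had a median of −1.41 (camera adjusted p 0.0110; p 0.658 with the estimated correlation), with Acan from 36.1 ± 8.95 to 13.5 ± 4.26 CPM and 3 of 7 past the threshold adjusted over the list alone; without femoral control replicate 1 the list stood at 0.0514. Cholesterol synthesis genes had a median of −0.16 (camera adjusted p 0.0180; p 0.734 with the estimated correlation), lost without femoral control replicate 1 (0.0630) or knockout replicate 2 (0.144). Unfolded protein response genes had a median of −0.20 (camera adjusted p 0.0362; p 0.734 with the estimated correlation), lost without femoral control replicate 1 (0.0802) or 2 (0.156) and without femoral knockout replicate 2 (0.0511) or 3 (0.261). Hspa5, the main chaperone of that list, went from 1250 ± 306 to 885 ± 67.5 CPM. These made 16 femoral lists called of 39 tested, and none with the estimated correlation.

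The remaining femoral lists did not pass camera. Their medians, each with its Benjamini-Hochberg adjusted p, were −0.24 for modulated smooth muscle (0.177), −0.13 for the cell cycle (0.234), 0.02 for matrix proteases (0.374), −0.10 for growth factors (0.374), 0.01 for the TRIM family (0.520), 0.02 for CNC factors (0.374), 0.07 for the antioxidant response (0.141), 0.02 for the proteasome (0.655), −0.03 for autophagy (0.374), −0.06 for oxidative phosphorylation (0.334) and −0.18 for immediate early genes (0.449). Among cell lists they were −0.10 for mast cells (0.718), −0.54 for lymphatic endothelium (0.301), −0.15 for adipocytes (0.374), −0.12 for brown adipocytes (0.918), 0.08 for Schwann cells (0.948), −0.30 for neurons (0.393), 0.05 for salivary gland (0.393), −0.84 for keratinocytes (0.491), 0.07 for platelets (0.681) and 0.20 for sex-linked genes (0.0766). Thyroid genes, with 2 members measured, were too few for camera. Median, mean or test differed in sign for the TRIM family, CNC factors, mast cells, brown adipocytes and Schwann cells. In the TRIM family 1 member rose and 4 fell over all genes, and 3 rose and 6 fell adjusted over the list alone. Adjusted over the list alone, 4 growth factor genes rose and 4 fell, 4 CNC genes rose and 1 fell, 3 antioxidant and 2 lipid handling genes rose and 1 modulated smooth muscle gene fell.

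In the ligated carotid artery, the lists of T and NK cell and of B and plasma cell genes stood higher in the knockout and those of the cell cycle and of cholesterol synthesis lower, by camera at its preset correlation. With the correlation estimated from the data these lists did not pass (Benjamini-Hochberg adjusted p 0.189, 0.189, 0.233 and 0.189, in that order). In fry, the other alternative, they did (adjusted p 0.00656, 0.00656, 0.026 and 0.00656). Unfolded protein response (fry adjusted p 0.0176) and sex-linked genes (0.0277) passed fry as well. T and NK cell genes had a median change of 2.20 on the log2 scale, with Cd3e from 0.851 ± 0.164 (SD, n = 3) to 5.67 ± 0.32 CPM (n = 2), and B and plasma cell genes a median of 3.04, with Igkc from 7.24 ± 2.89 to 80.3 ± 6.34 CPM. All 37 cell cycle genes had negative changes, with a median of −0.81, and Ccna2, a cyclin of S phase and mitosis, fell from 45.7 ± 8.42 to 25.5 ± 3.96 CPM. Cholesterol synthesis genes had a median of −0.45, and Fdps fell from 46.6 ± 1.31 to 25.1 ± 1.68 CPM. Of 21343 genes, 141 rose and 56 fell at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test, 126 and 23 of them by at least 2-fold.

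Carotid genes were ranked within the naming rule, at 5 CPM or more and with predicted genes left out, some of which changed further. The largest rises included those of Hal (9.19 ± 0.73), Gbp2b (6.93 ± 1.24) and Pydc3 (5.08 ± 0.68). Others were the organic cation carrier Slc22a3 (3.98 ± 0.52), Gdpd3 (3.86 ± 0.46), Ubd (3.79 ± 0.66) and the phosphate hormone Fgf23 (3.75 ± 0.66). Besides Trim5 and Trim34a, the largest falls within that rule were the small RNA Bc1 (−1.99 ± 0.38), the clock factor Arntl (−1.73 ± 0.25) and Wnt2 (−1.60 ± 0.29). Cyr61 (−1.59 ± 0.23), Mrps12 of the mitochondrial ribosome (−1.35 ± 0.11) and the Wnt receptor Fzd8 (−1.26 ± 0.23) followed. Cyr61, a matrix protein induced by stretch and growth signals, went from 462 ± 123 to 153 ± 40.2 CPM. The 197 calls became 60 without carotid control replicate 3, 76 and 128 without carotid knockout replicate 1 or 2, and 130 without femoral knockout replicate 2, which enters through the spread shared by all groups. Without carotid control replicate 2 the balance of calls turned to 93 rises and 101 falls. Among 41 named genes, 11, 9 and 20 carotid calls ended without carotid control replicate 1, 2 or 3, and 22 and 18 without knockout replicate 1 or 2. With only the carotid libraries in the fit 26 genes passed and 31 of the 40 named calls ended. With the replicate numbers of the titles as a block 78 genes passed and 20 of the 40 ended, and with those of the descriptions 197 passed and 12 ended.

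T and NK cell genes rose as a set in the carotid knockout (camera, Benjamini-Hochberg adjusted p 3.61e-19; p 0.189 with the correlation estimated from the data), with 9 of 18 called and 17 adjusted over the list alone. Themis (3.51 ± 0.35), Cd3e (2.73 ± 0.30), Cd5 (2.43 ± 0.37) and the kinase Lck (2.17 ± 0.30) led them, and Cd8a and Cd8b1 of cytotoxic T cells rose by 3.20 and 3.11. B and plasma cell genes followed (camera adjusted p 5.75e-12; p 0.189 with the estimated correlation), with 6 of 14 called and 12 adjusted over the list alone, led by Ighd (3.86 ± 0.55), Jchain (3.69 ± 0.52), Igkc (3.47 ± 0.44) and Ighm (1.63 ± 0.19). Their mean log2 level was 0.41, 0.11 and 0.24 in the carotid controls and 2.18 and 3.24 in the knockouts. Lymphatic endothelial genes stood at 1.43, 2.09 and 2.46 in the same controls and at 2.51 and 3.89 in the knockouts. Of their 7 genes 3 were higher adjusted over the list alone, and the list did not pass camera (adjusted p 0.151). Interferon response genes were all 40 positive (median 0.74, camera adjusted p 7.13e-10; p 0.810 with the estimated correlation), and Ifit2 was the 1 member called, from 28.1 ± 2.88 to 60.2 ± 6.08 CPM, also adjusted over the list alone. Cytokine genes had a median of 0.47 (camera adjusted p 0.00774; p 0.934 with the estimated correlation) and Ccl5 rose by 1.38 ± 0.26, the 1 call over all genes and adjusted over the list alone. Ptgs2 went from 180 ± 49.0 to 86.5 ± 18.9 CPM, against the direction of its list. The cytokine call was lost without carotid control replicate 3 (adjusted p 0.192) or knockout replicate 1 (0.773). Neutrophil genes had a median of 0.81 (camera adjusted p 0.0150; p 0.832 with the estimated correlation), with Lcn2 from 32.7 ± 16.8 to 192 ± 14.9 CPM; that call was lost without carotid control replicate 3 (0.222) or knockout replicate 2 (0.0837).

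Cell cycle genes fell as a set in the carotid knockout (camera adjusted p 1.63e-22; p 0.233 with the estimated correlation). Birc5 (−0.94 ± 0.17), E2f1 (−0.85 ± 0.16) and Ccna2 (−0.84 ± 0.16) passed over all genes and 35 of 37 adjusted over the list alone, and Top2a went from 102 ± 27.3 to 55.7 ± 2.05 CPM. Cholesterol synthesis genes fell as well (camera adjusted p 1.63e-11; p 0.189 with the estimated correlation), with 5 of 20 called and 14 adjusted over the list alone. Cyp51 fell by 0.99 ± 0.13, Idi1 by 0.96 ± 0.18, Fdps by 0.89 ± 0.11, Sqle by 0.77 ± 0.12 and Msmo1 by 0.72 ± 0.12, all enzymes between mevalonate and cholesterol. Unfolded protein response genes had a median of −0.34 (camera adjusted p 1.69e-09; p 0.233 with the estimated correlation), with none called over all genes in edgeR's quasi-likelihood test and 16 of 25 adjusted over the list alone; Hyou1 went from 252 ± 22.8 to 158 ± 20.2 CPM and Creld2 from 90.7 ± 2.90 to 51.3 ± 4.56 CPM. Proteasome subunits were all 34 negative, with a median of −0.16 (camera adjusted p 3.71e-05; p 0.832 with the estimated correlation) and Psmd8 from 169 ± 10.6 to 124 ± 9.28 CPM. Immediate early genes were all 22 negative, with a median of −0.84 (camera adjusted p 2.52e-07; p 0.632 with the estimated correlation), and Fosb went from 155 ± 158 to 20.8 ± 2.54 CPM, a spread among the controls as large as their mean. Collagen and elastic matrix genes had a median of −0.18 (camera adjusted p 0.00538; p 0.886 with the estimated correlation), not called without carotid knockout replicate 2 (0.125); Serpinh1 went from 2420 ± 39.0 to 1680 ± 114 CPM and Tnc from 530 ± 61.7 to 316 ± 8.26 CPM. Lipid handling genes had a median of 0.36, with Abcg1 from 36.0 ± 5.46 to 61.7 ± 0.834 CPM (camera adjusted p 0.00188; p 0.610 with the estimated correlation; 0.0602 without carotid knockout replicate 1).

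Genes of other tissues also moved in the carotid libraries. Neuron genes had a median of 2.71 (camera adjusted p 0.00489; p 0.810 with the estimated correlation), from a mean log2 level of 4.08 in carotid knockout replicate 1 against 0.21 in replicate 2 and −1, 0.22 and 1.70 in the controls. Without that replicate the neuron list turned negative (adjusted p 0.773), and without carotid control replicate 1 its adjusted p was 0.0892. Schwann cell genes had a median of −1.63 (camera adjusted p 0.000516; p 0.810 with the estimated correlation), with Mbp from 168 ± 153 to 38.8 ± 27.9 CPM; the call was lost without carotid knockout replicate 2 (adjusted p 0.238). Sex-linked genes had a median of 0.34 (camera adjusted p 0.0240; p 0.308 with the estimated correlation), lost without carotid knockout replicate 2 (0.252), where Xist had 54 counts beside 5 in replicate 1 and 2, 1 and 0 in the controls. These made 15 carotid lists called of 39 tested, and none with the estimated correlation.

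The remaining carotid lists did not pass camera. Their medians, each with its Benjamini-Hochberg adjusted p, were −0.09 for contractile smooth muscle (0.571), 0.05 for modulated smooth muscle (0.963), 0.07 for matrix proteases (0.636), −0.03 for growth factors (0.885), −0.04 for the TRIM family (0.843), 0.06 for CNC factors (0.833), 0.08 for the antioxidant response (0.422), 0.17 for NADPH oxidase (0.422), 0.10 for autophagy (0.0923), −0.07 for oxidative phosphorylation (0.149) and −0.04 for glycolysis (0.843). Among cell lists they were 0.12 for macrophages (0.190), 0.18 for mast cells (0.571), 0.13 for endothelium (0.0705), 0.37 for lymphatic endothelium (0.151), 0.02 for adventitial fibroblasts (0.833), 0.15 for adipocytes (0.535), 0.41 for brown adipocytes (0.571), −0.14 for skeletal muscle (0.393), −0.78 for salivary gland (0.868), 2.09 for keratinocytes (0.0914), −0.16 for cartilage (0.827), −0.36 for erythrocytes (0.228) and 0.31 for platelets (0.393). Modulated smooth muscle, growth factors and CNC factors had a median, mean or test of differing sign. Hgf rose by 0.86 ± 0.14 among the growth factors, of which 3 rose adjusted over the list alone, and in the TRIM family 2 members rose and 2 fell, with 6 and 5 adjusted over the list alone.

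**Figure D2:**
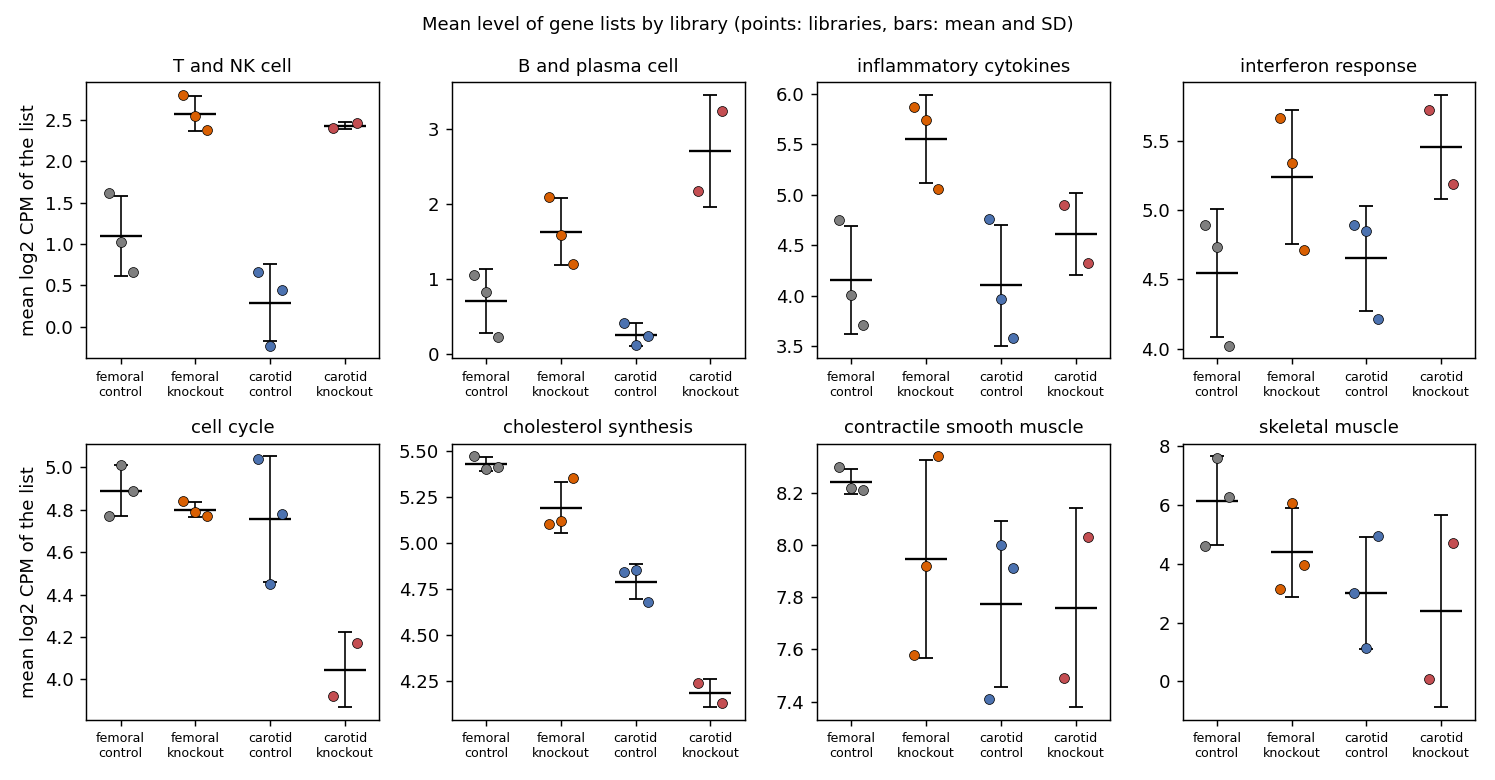
Mean level of 8 gene lists in each library, in log2 CPM, with the mean and SD of each group. T and NK cell genes lay at 2.38 to 2.80 in the 5 knockout libraries and at −0.23 to 1.62 in the 6 controls.

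Of 535 femoral and 197 carotid calls, 98 were shared in the same direction. They include predicted genes and pseudogenes, which the naming rule left out. Pseudogenes were 4.9% of femoral and 10.2% of carotid calls, against 4.7% of genes tested. With protein-coding genes only, a setting chosen after the data were seen, 58 calls were shared. The shared number was 19 with only the libraries of each comparison in the fit. With the replicate numbers of the titles or the descriptions as a block it was 61 or 113. The 2 comparisons share no library, though the labels do not say whether the vessels share animals or days, and cytokine genes averaged 4.75, 4.01 and 3.71 log2 CPM in femoral controls 1 to 3 beside 4.76, 3.97 and 3.58 in the carotid controls. In all, 78 genes rose in both where 2.6 were expected if genes and vessels were independent, and 20 fell in both against 0.373 (Fisher's exact test across genes, p 5.06e-99 and 4.62e-30, described only, since neither need hold). In limma-voom 87 calls were shared, and 90 with same-numbered libraries of the vessels allowed to correlate, a fit chosen after the data were seen. Hal went from 0.064 ± 0.063 to 38.3 ± 18.1 CPM in the carotid artery, beside 0.108 to 13.8 CPM in the femoral artery. Nnt, the mitochondrial proton-pumping transhydrogenase, fell from 58.6 ± 5.63 to 29.7 ± 3.24 CPM and from 59.3 ± 3.42 to 30.9 ± 0.823 CPM. Mrps12 fell from 21.0 ± 1.78 to 8.65 ± 0.0841 CPM and from 22.0 ± 0.657 to 8.63 ± 0.198 CPM.

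Other shared genes of small p were the innate immune kinase Alpk1 (1.71 ± 0.16 and 1.23 ± 0.17, femoral then carotid), Mocs1 of molybdenum cofactor synthesis (0.63 ± 0.09 and 0.82 ± 0.10), and Gdpd3, Jchain, Trim34b and Trim5, whose values stand with each vessel. The circadian factor Arntl also fell in both, by 1.79 ± 0.22 and 1.73 ± 0.25. Of the 535 femoral calls 471 (88.0%) had the same sign in the carotid artery, and of the 197 carotid calls 189 (95.9%) had the same sign in the femoral artery, against 61.9% of all genes. Across genes the changes correlated with a Pearson r of 0.46 and a Spearman rho of 0.294. The 98 shared calls were 44, 48, 51 and 54 without femoral control replicate 2 or 3 or femoral knockout replicate 1 or 2, and 42, 43 and 63 without carotid control replicate 3 or carotid knockout replicate 1 or 2. Of the 98, 4 lay in the segment of chromosome 7 from 103718782 to 105007849 (GRCm38) that holds Trim5, where 19 genes were tested. A wider stretch around it, from 102470456 to 106644646, held 7 shared calls among 50 tested genes. No other run of shared calls spaced within 2 Mb held as many. Chromosome 7 as a whole had 15 shared calls, 0.91% of its tested genes, beside 0.89% on chromosome 19 and lower shares elsewhere.

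**Figure D3:**
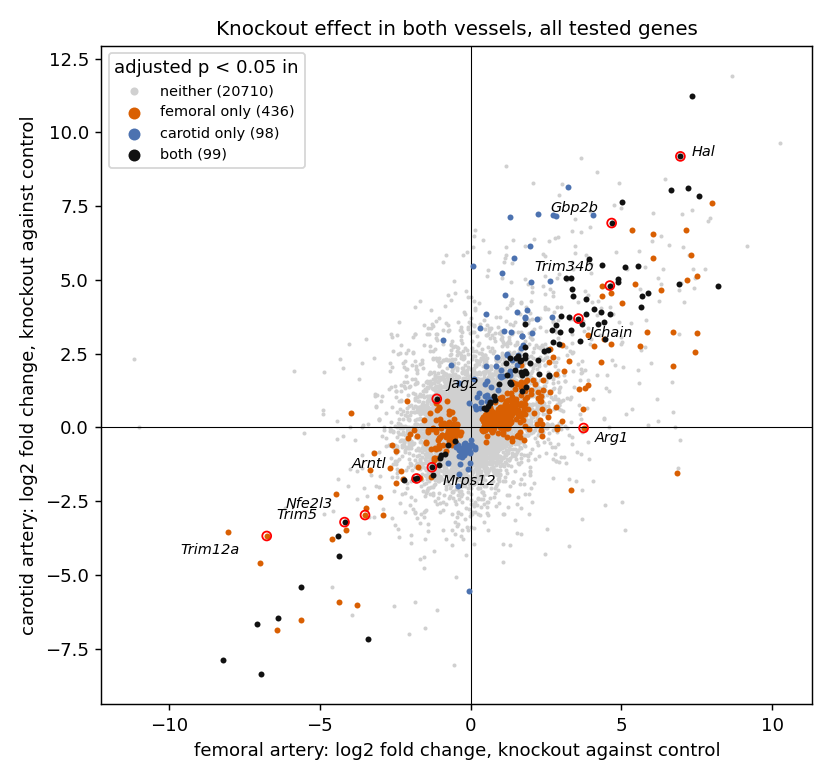
Knockout effect of each tested gene, with the femoral log2 fold change on the horizontal axis and the carotid log2 fold change on the vertical axis. The 98 genes called in both in 1 direction lie in the upper right and lower left, with Hal at 6.96 and 9.19 and Trim5 at −4.18 and −3.21, and Jag2 lies apart at −1.12 and 0.97.

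The knockout effect differed between the vessels for 1 gene, the Notch ligand Jag2. Jag2 fell from 57.5 ± 12.7 to 26.5 ± 2.60 CPM in the femoral artery (−1.12 ± 0.15, adjusted p 0.00716) and rose from 13.4 ± 1.24 to 26.3 ± 0.58 CPM in the carotid artery (0.97 ± 0.17, adjusted p 0.0254). The difference was 2.09 ± 0.22 (edgeR's quasi-likelihood test of the interaction, Benjamini-Hochberg adjusted p 0.0394), and the knockouts of both vessels ended at a like level. It stayed past the threshold without femoral control replicate 2 (adjusted p 0.0308) or 3 (0.00865) and missed it without any 1 of the other 9 libraries (0.0690 to 0.185), with its direction kept. It also missed the threshold with the replicate block by title (adjusted p 0.0569) or description number (0.0866), in limma-voom (0.0898) and with the skeletal muscle covariate (0.0626). The carotid Jag2 call itself was also lost with either replicate block and when any 1 carotid library was left out. At an unadjusted p under 0.05 in the test of the difference there were 1815 genes.

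Gene lists set the vessels further apart. Cytokine genes stood 1.08 lower in the carotid than in the femoral response (camera, Benjamini-Hochberg adjusted p 6.23e-06), and cell cycle genes 0.65 lower (adjusted p 5.68e-16); with the estimated correlation both had p 0.652. Arg1, which rose in the femoral knockout, went from 50.5 ± 32.9 to 49.9 ± 19.5 CPM in the carotid artery. B and plasma cell genes stood higher in the carotid response, with a median difference of 1.52 (adjusted p 1.06e-05), as did endothelial genes, with 0.44 (adjusted p 1.06e-05), and Kdr changed by −0.44 in the femoral and 0.70 in the carotid artery; the estimated correlation gave p 0.652 for each. No list member passed singly over all genes in edgeR's quasi-likelihood test of the difference.

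The control vessels differed from each other in 1326 genes, 639 higher and 687 lower in the carotid than in the femoral artery, which gives the background for the knockout comparisons. Vessel, injury and surrounding tissue differ together here. Postn stood at 3260 ± 480 CPM in the carotid and 796 ± 181 CPM in the femoral controls (2.04 ± 0.23), and Cthrc1, a matrix gene of injured arteries, was higher by 2.19 ± 0.36. Desmin, Des, was lower, at 43.3 ± 22.3 against 429 ± 44.5 CPM, and lymphatic Mmrn1 stood at 0.329 ± 0.204 against 55.2 ± 6.03 CPM. At least 2-fold differences made up 389 and 463 of the calls (edgeR's quasi-likelihood test, Benjamini-Hochberg).

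Cholesterol synthesis genes were lower in the carotid controls (median −0.67, camera adjusted p 1.71e-12; p 0.240 with the estimated correlation), with 11 of 20 called and 18 adjusted over the list alone, among them Fdps (−0.99 ± 0.10), Cyp51 (−0.96 ± 0.12) and Msmo1 (−0.78 ± 0.11). Contractile genes were lower (−0.45, adjusted p 0.00800; p 0.787 with the estimated correlation), with Pln at −2.01 ± 0.33, while Itga8 was higher by 1.20 ± 0.23; adjusted over the list alone, 2 were higher and 8 lower. Collagen and elastic matrix genes were higher (0.17, adjusted p 0.0230; p 0.787 with the estimated correlation), though Col8a1 was lower by −1.87 ± 0.25. Lymphatic genes were lower (−1.66, adjusted p 6.45e-05; p 0.310 with the estimated correlation), with Prox1 at −4.69 ± 0.49 and Flt4 at −1.66 ± 0.22. The other lists passing camera each had p of 0.748 to 0.787 with the estimated correlation. Among these, skeletal muscle (−3.04, adjusted p 1.37e-05), adipocyte (−1.40, 3.47e-05), erythrocyte (−1.39, 0.000818), T and NK cell (−0.97, 0.000174), endothelial (−0.38, 0.000174) and oxidative phosphorylation genes (−0.19, 0.00298) were lower. Schwann cell (2.92, 0.000174), brown adipocyte (1.10, 0.0214), immediate early (0.64, 0.000875), macrophage (0.43, 0.000585) and unfolded protein response genes (0.27, 0.000174) were higher. Immediate early genes averaged 6.51, 7.38 and 6.14 log2 CPM in carotid controls 1 to 3, and 6.10, 6.10 and 6.04 in the femoral controls. Lists passing camera as higher in the carotid controls numbered 6, with 3 without carotid control replicate 2 and 9 without replicate 3. Single members called include Mbp (3.04), Ucp1 (6.49), Retn (−3.37), Cfd (−2.65), Pygm (−2.32), Cldn5 (−1.38), Nos3 (−0.90), Fosb (3.00), Itgam (0.91), Hyou1 (0.56) and Alas2 (−1.37). The 1326 calls were 867, 685 and 862 without femoral control replicate 1, 2 or 3, and 876 and 875 without carotid control replicate 2 or 3. Matrix proteases, modulated smooth muscle, cytokines, NADPH oxidase and glycolysis, none of which passed, had a median, mean or test of differing sign.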

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

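The skeletal muscle covariate was chosen after the result was seen and the other tests were fixed in advance, and no explanation of these differences was tested. The knockout effect on Jag2 differed between the vessels by 2.09 on the log2 scale, carotid minus femoral, by edgeR's test of the interaction (Benjamini-Hochberg adjusted p 0.0394). Jag2 was lower in all 3 femoral knockouts and higher in both carotid knockouts than in any control of the vessel. The difference missed the threshold in limma-voom (adjusted p 0.0898), with the replicate blocks (0.0569 and 0.0866) and with the skeletal muscle covariate (0.0626). Omission of single libraries moved it from 0.00865, without femoral control replicate 3, to 0.185.

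The other 17 differences between the vessels are those of gene lists that passed camera in the test of the interaction, given as median carotid minus femoral effect. Lists lower in the carotid response were inflammatory cytokines (−1.08, adjusted p 6.23e-06), cell cycle (−0.65, 5.68e-16), immediate early genes (−0.72, 0.000277), cholesterol synthesis (−0.32, 1e-05), proteasome (−0.18, 7.66e-05), unfolded protein response (−0.18, 0.000405), glycolysis (−0.17, 0.0272) and Schwann cell and nerve (−1.56, 0.00382). Lists higher in the carotid response were B and plasma cell (1.52, 1.06e-05), T and NK cell (0.76, 0.00324), endothelial (0.44, 1.06e-05), lymphatic endothelial (0.97, 0.0272), adventitial fibroblast (0.36, 0.0348), autophagy (0.14, 0.0204), neuron (2.82, 0.0011), keratinocyte (1.73, 0.0272) and cartilage (1.04, 0.0379). With the correlation estimated from the data none of the 17 passed, with p from 0.652 upward, and none passed in fry. The neuron difference comes from carotid knockout replicate 1, whose mean log2 level of neuron genes was 4.08, and keratinocyte genes stood at 2.33 in carotid knockout replicate 2. Matrix proteases, which did not pass, had a median difference of 0.07 and a test in the other direction. A difference between the wire-injured femoral and the ligated carotid artery cannot be assigned to vessel or injury, because the samples hold each injury in 1 vessel only.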

How the results depend on the processing

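The skeletal muscle covariate, the fit of protein-coding genes only and limma-voom with same-numbered libraries of the vessels allowed to correlate were tests chosen after the data were seen; the other settings were planned. Of the named gene results under settings other than leaving out 1 library, 1099 kept direction and side of the threshold, 167 kept direction but missed it, 11 newly passed it and 0 reversed. Of the 167, 15 femoral and 31 carotid results come from fits of only the libraries compared, and 33 femoral from the covariate. With 1 library left out these numbers were 764, 331, 5 and 0. The 1 reversal was that of the list neuron, carotid artery, without carotid knockout replicate 1 (adjusted p 0.773, from 6.03e-10 upward over all libraries left out).

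The 535 femoral calls were 1121 with no filter beyond 1 read, 1834 in DESeq2, 1224 and 1261 with the replicate block by title or description, 345 at 2-fold or more, 143 with the skeletal muscle covariate, and 78 to 1317 with 1 library left out. The 197 carotid calls were 444 with no filter, 72 at a mean of at least 5 CPM, 990 in DESeq2, 78 and 197 with the blocks by title or description, 26 with only the libraries compared, 131 for protein-coding genes only, and 60 to 233 with 1 library left out. The 98 shared calls were 200, 36, 340, 61 and 113, 19 and 58 under the same settings in that order, 59 with the covariate, and 42 to 130 with 1 library left out. The 1 difference between vessels was 17 with no filter, 171 in DESeq2, 0 in limma-voom, 9 and 3 with the blocks, 0 with the covariate and 0 to 3 with 1 library left out. At unadjusted p under 0.05 there were 1815. The 9 and 3 do not include Jag2 (adjusted p 0.0569 and 0.0866). The 1326 calls between controls were 831 at 5 CPM, 2314 in DESeq2, 852 at 2-fold, 600 with the covariate and 685 to 1408 with 1 library left out. Between the vessels, deviations of same-numbered control libraries correlated with r of 0.11, −0.04 and 0.14. For the knockouts r was 0.13 and 0.1 (0.03 for the last by description number). Libraries of differing title number had r of −0.15 to 0.03. A pairing of the vessels by number can therefore not be excluded, and the main fit took the vessels as independent. Allowing same-numbered libraries to correlate in limma-voom (estimate 0.154) gave 570 femoral, 142 carotid, 90 shared, 0 difference and 1709 control calls. Without it these were 542, 138, 87, 0 and 1257. Calls under only the libraries compared rest on fewer samples; for the other settings the cause was not tested.

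Nfe2l3 in the femoral artery missed the threshold with the title block (−3.80, adjusted p 0.0501) but not the description block (−3.79, 0.0492). It also missed it with only the libraries compared (−3.50), the covariate (−3.55) and protein-coding genes only (−3.48), and ran from −5.48 to −2.90 with 1 library left out; in the carotid artery it passed in DESeq2 (−3.00) and ran from −3.10 to −2.86. It gave no value under the 5 CPM filter, and the difference between vessels gave none under only the libraries compared; pseudocounts were not run, since the values are counts. With the estimated correlation 0 of 16 femoral, 0 of 15 carotid, 0 of 17 difference and 0 of 15 control lists passed, and in fry 1, 6, 0 and 2. With 1 library left out, 12 to 18 femoral, 13 to 18 carotid, 12 to 18 difference and 13 to 18 control lists passed. The carotid Jag2 call missed the threshold with the title block (adjusted p 0.0828) and the description block (0.0686), and its range with carotid libraries left out was 0.0562 to 0.105. The skeletal muscle covariate ended the femoral calls of contractile smooth muscle (0.0723), NADPH oxidase, macrophage and unfolded protein response (0.0737 each) and skeletal muscle (0.121). Group means of Nfe2l3, 0.0926 to 1.36 CPM, are few counts, and whether this makes its call depend on the setting was not tested.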

Other observations

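Chosen only after the result was seen were the tests of reads shared between paralogs and of depth for Trim5 and Trim12a, the grouping of immunoglobulin, T cell receptor and MHC families in the test of positions, and its repeat on named genes. Xist, the RNA of the inactive X chromosome, had 45, 36 and 14 counts in the femoral knockouts against 14, 6 and 6 in the controls, while every library expressed Ddx3y of the Y chromosome at 96.3 to 114 CPM. Lymphatic Ccl21a stood at 0.606 ± 0.776 CPM in the carotid controls and 19.1 ± 25.5 CPM in the carotid knockouts, beside 140 ± 21.9 CPM in the femoral controls. Brown fat Ucp1 stood at 109 ± 134 CPM in the carotid knockouts, and Krt5 of keratinocytes at 7.04 ± 9.78 CPM.

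Arntl fell by 1.79 in the femoral and 1.73 in the carotid artery, and Npas2 fell by 2.48 in the femoral artery (adjusted p 0.0361) and had −1.90 in the carotid artery (adjusted p 0.150). Clock, Cry1 and Nfil3, which peak near Arntl, had medians of −0.26 and −0.61, none of them called. Femoral changes of Cry1 (−0.08 ± 0.26) and Nfil3 (−0.26 ± 0.23) were small beside their SE, so these genes decide little. Clock, Cry1 and Nfil3 were the test of a change of Arntl and Npas2 alone, and that test therefore cannot decide. The genes of opposite phase, set as the test of another time of day only, moved as well. Whether their change follows from lower Arntl and Npas2 was not tested, so a change that starts with Arntl and Npas2 stays open. The 10 genes of opposite phase had positive changes in both vessels, with medians of 1.08 and 1.3; Per1 (1.01) passed in the femoral artery, and Per3 (1.78) and Bhlhe41 (1.05) in the carotid artery. Control replicate 2 stood apart in both vessels, with Dbp at 41.5 and 42.3 CPM against 6.99 to 11.1 in the other controls, and Nr1d1 at 132 CPM in carotid control replicate 2, above the 102 of carotid knockout replicate 2. These values are consistent with tissue taken at another time of day, which the labels do not give, while an effect of Nrf3 loss on the clock was not tested and stays open.

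Trim5 and Trim12a lost 24.9 CPM in the femoral and 22.6 CPM in the carotid knockouts, and Trim12c gained 24.7 and 32.4 CPM. Lower depth is argued against, since the lowest knockout total was 0.86 of the lowest control total. The sum of the 3 genes changed by −0.01 and 0.21 on the log2 scale, as it could if reads moved between paralogs. A separate rise of Trim12c beside a fall of the other 2 could also leave the sum level, so the sum cannot decide. In the carotid artery the gain was larger than the loss. Whether a strain variant or copy difference in this cluster moved reads was not tested. A move of reads among these 3 genes does not cover Trim34a and Trim34b, whose sum changed by −1.15 and −0.76. Trim30d (−1.75, edgeR adjusted p 0.0353, and −1.33, 0.146) and Trim30b (−1.59 and −2.17, neither called) also fell. Their paralog Trim30c was higher in the knockouts, at 3.27 to 6.22 against 1.16 to 2.93 CPM in the femoral artery. In the carotid artery it was at 4.7 and 17.9 against 3.14 to 4.06 CPM. Trim30a had 37 to 67.8 against 30.6 to 53.3 CPM in the femoral artery. The Trim30 genes were not summed, so a move of reads among them was not tested. A fall of Trim5 through loss of Nrf3, the axis that the series title names, was not tested apart from moved reads and stays open.

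Calls shared by both vessels may include genes near DNA that differs between the knockout and control mice. Outside the Trim5 cluster, 30 of 94 shared calls (31.9%) had another of a different family within 2 Mb, against a median of 20 and a 95th percentile of 29 in 10000 draws matched on expression (share as large 0.0397); without predicted genes it was 15 of 64 against 10 and 17 (share 0.128). A looser rule for families, used at the start, gave 35 and 20; the stricter rule, and the demand that named genes alone also exceed their 95th percentile, came after that count was seen, and on the criterion as written at the start 30 exceeds 29. Nnt, which is deleted in part in C57BL/6J mice but not in C57BL/6N mice, was among the shared falls. Segments that differ cannot be told apart from an effect of Nrf3 loss here, since the labels give no mouse background, and a background that differs with genotype would mark the same libraries. Within 10 Mb of Nfe2l3 there were 0 shared calls among 156 tested genes, against 0.463% elsewhere (one-sided Fisher's exact test p 1), too few to decide on DNA flanking the targeted gene on chromosome 6.

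For the counts of calls, each comparison was refitted on its own libraries in all 10 splits into groups of the same sizes. The real split gave 424 femoral, 26 carotid and 1187 control calls, and the highest other split gave 0 in each; 1 of 10 splits was as large in each, the real one, and 10 splits cannot give a share under 0.05.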
